A study of Homo sapiens with 33 samples.

How the data were processed

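RNA of human colon biopsies was measured on Affymetrix expression arrays in 33 samples. The labels put 8 samples in the group REF, 11 in Crohn's disease (CD), 9 in treated CD and 5 in ulcerative colitis (UC). The design text adds that the CD and UC biopsies were taken at diagnosis, that the treated CD biopsies were taken during therapy, and that tissue came from the part of the colon nearest its proximal end that was affected. REF is not spelled out in the labels. The design text names healthy controls as the remaining group, and REF was read as that group. Per the labels, 100 ng of total RNA was amplified and turned into biotinylated cRNA.

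The submitters' processing notes name RMA, a method that corrects background, normalises and summarises probes. Its version, the probe set definition and any filter are not given in the sources used here. The authors deposited values normalised with internal control arrays, which the design text places in batches 1 to 4, and each deposited value was read as a ratio to them. The control arrays themselves were not used here. Which sample belonged to which batch is not given in the sources used here, nor what RNA the control arrays held. The ratio was taken as linear because every value was positive, the median ratio of a sample lay between 0.928 and 1.12, and the lowest value was 0.01. That lowest value was reached 32 times, in 17 of 26121 probe sets, and the highest ratio was 1018.64. A ratio holds no expression level, so a gene can be compared between samples but not with another gene. The number of arrays limits the precision, and nothing in the labels says that samples of a group came from separate persons, so p-values measure the spread between these samples.

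Probe sets carry RefSeq transcript identifiers, which were matched to gene symbols of the human annotation on GRCh38.p14. The annotation was used for names only. Of the 26121 probe sets, 20443 (78.3%) matched 1 symbol, 0 matched several and 5678 matched none. The ratios were taken to log2. The SD of the probe set medians was 0.36 log2, so each gene received the mean of its probe sets, a rule set for values scaled to a reference. This gave 15978 genes, of which 2888 had more than 1 probe set. Values of 37 genes were kept out of all tables to protect the donors. TNF was not analysed here.

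Groups were compared with limma 3.58.1 in R 4.3.3, in a single fit of all 33 samples with 4 group means, empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes. A gene counted as changed at an adjusted p under 0.05. The 5 comparisons were CD with REF, UC with REF, CD with UC, treated CD with CD, and treated CD with REF. Differences are log2 differences with their standard error (SE), and group values are mean log2 ratios with their standard deviation (SD). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and drew the plots. The procedure was tested on simulated data with 50 genes shifted by each of 1, 2, 3 and 4 log2. It recovered between 80% and 96% of the genes shifted by 1 and between 92% and 100% of those shifted further. Among unchanged genes it called between 6 and 12 per comparison. The simulated noise was independent between genes and samples and held no clusters. It therefore cannot show how many unchanged genes are called in these data.

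Gene sets, 30 in number, covered inflammation (the IL-6/STAT3 pathway and its targets, cytokines of the Th17, TNF and IL-1 axes, chemokines, epithelial antimicrobial defence, matrix proteases, collagens and extracellular matrix, interferon-gamma response, type I interferon response), cell types (neutrophils, T cells, B and plasma cells, monocytes and macrophages, mast cells and eosinophils, endothelium, smooth muscle with fibroblasts and glia, mature colonocytes, goblet cells, enteroendocrine cells), epithelial metabolism (xenobiotic, steroid and lipid metabolism, butyrate uptake and fatty acid oxidation, the mitochondrial respiratory chain), cell state (proliferation, unfolded protein response, glucocorticoid-responsive genes, immediate early genes), and checks of the sample (globin, ileal and Paneth markers, distal and proximal colon position, housekeeping). Each was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison, then again with a correlation estimated from the data, and with fry. In the 5 comparisons 0 list calls held with the estimated correlation. On simulated data with the proliferation list shifted by -1 log2, both forms of camera found it in every comparison, and camera called 1 other list in the comparison of CD with UC and 0 in the others. Genes were independent in that simulation, so it cannot show how often unchanged lists of correlated genes are called.

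The named genes are the 8 with the largest positive and the 8 with the largest negative difference among those that passed (4 each way for treated CD with REF), up to 4 passing members of each list described (the 2 members with the largest difference where fewer passed), and IL6, STAT3, SOCS3, IL6R, IL6ST and IL17A in CD and in UC whatever their values. A few genes that this rule picks were not used here. Some further list members, named as such, were picked after their values were seen. Groups, comparisons, tests, lists, this naming rule and the following alternatives were fixed before the data were examined. These alternatives were quantile normalisation, centring of arrays, probe sets in place of genes, the most variable probe set per gene, a filter on genes with little variation, a fold limit of 1.5, array weights, a trended and robust variance, a fit of 2 groups only, the replicate number as a block, and leaving out each sample.

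The labels give no batch. Samples were therefore clustered (average linkage on 1 minus Pearson's r) over the 7837 probe sets with the least variation, 30% of all, after the data had been seen. The number of clusters was set to 4, so that number is not a result. With 10%, 20%, 40% and 50% of the probe sets the 4 clusters came out alike. Every comparison was refitted with these clusters as a block, and the report gives values with clusters as a block beside many of the pooled ones. No cluster held REF together with UC or treated CD, so block values of UC and of treated CD against REF are indirect. They run through CD, which had 1 sample in cluster 3 and 2 in cluster 4. Genes counted for keeping their direction with clusters as a block were picked by the pooled fit of the same samples, which favours the same direction. Permutation tests over samples used 100000 resamples, or all arrangements where they were few.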

Results

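Gene expression was measured in 33 human colon biopsies, 8 REF, 11 from Crohn's disease (CD) at diagnosis, 9 from CD during therapy and 5 from ulcerative colitis (UC) at diagnosis. Every value was the log2 ratio of a sample to the authors' internal control arrays. The median ratio of a sample ran from 0.928 to 1.12, and the middle 50% of its probe sets spanned between 0.27 log2 (treated CD replicate 1) and 0.88 log2 (REF replicate 8). No 2 samples were copies of each other, the closest pair correlating at r = 0.889 across probe sets.

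The samples were cut into 4 clusters, a set number, over the least variable probe sets, and the clusters did not follow the groups alone. Cluster 1 held 5 REF and 7 CD samples, cluster 2 held 3 REF and 1 CD, cluster 3 held 1 CD and 5 treated CD, and cluster 4 held 2 CD, 4 treated CD and 5 UC. No cluster held REF together with UC or with treated CD. The median correlation was 0.26 between samples of one group and cluster (61 pairs), -0.08 between samples of one group in separate clusters (68 pairs), and 0.21 between samples of separate groups in one cluster (81 pairs). The clusters were built from these correlations, so higher values within a cluster were fixed in advance. PRAC1, a gene of the distal colon, and OLFM4, a marker of crypt base cells, moved with the clusters. In clusters 1 and 2 PRAC1 ranged from -4.63 to 2.98, and in clusters 3 and 4 from -0.48 to 7.30. OLFM4 ranged from 1.15 to 7.71 in clusters 1 and 2 and from 1.15 to 1.91 in clusters 3 and 4.

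**Figure D1:**
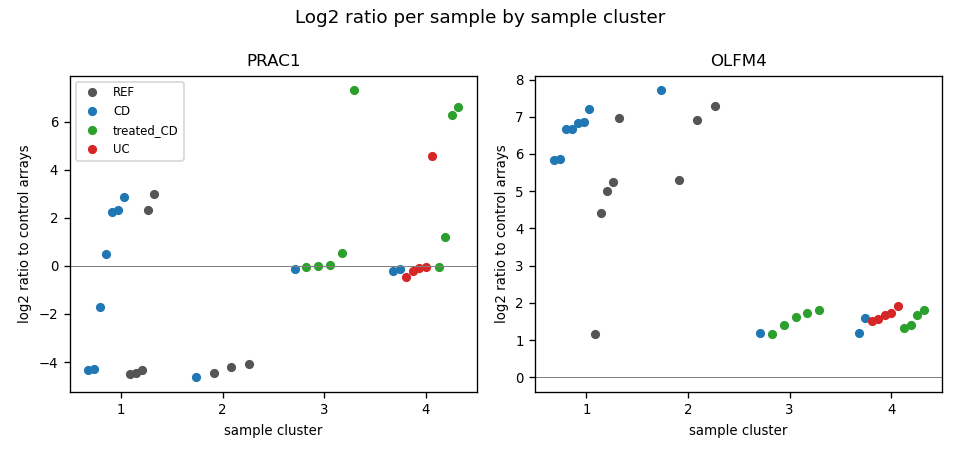
Log2 ratio to the control arrays (vertical axis) of PRAC1 and OLFM4 in each sample, by sample cluster (horizontal axis, clusters 1 to 4), with 1 point per sample coloured by group and no error bars. OLFM4 spans 1.15 to 1.91 in clusters 3 and 4, and PRAC1 shifts upward at both ends from clusters 1 and 2 to clusters 3 and 4.

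CD at diagnosis was compared with REF to see what the disease changed in the colon. DUOX2, an oxidase that releases hydrogen peroxide at the epithelial surface, rose 14.7-fold, from 0.56 ± 1.59 (SD, n = 8) in REF to 4.45 ± 1.10 (SD, n = 11) in CD (log2 difference 3.88 ± 0.74 (SE), adjusted p = 0.0237), and all 11 CD samples lay above the REF mean. CXCL1, which attracts neutrophils, rose by 2.72 ± 0.62 (SE, adjusted p = 0.0376, 11 of 11 samples). MEP1B, a protease of the enterocyte brush border, fell from 1.62 ± 1.48 (SD, n = 8) to -1.41 ± 0.98 (SD, n = 11), a log2 difference of -3.03 ± 0.54 (SE, adjusted p = 0.0165, 11 of 11 samples). Within REF, MEP1B was 0.27 and -1.36 in replicates 6 and 7, where PRAC1 was 2.34 and 2.98. In the other REF samples (PRAC1 from -4.50 to -4.08) MEP1B was 1.71 to 3.07. CD replicates 7, 9 and 11, with PRAC1 from -4.63 to -4.30, had MEP1B at 0.12, -0.24 and -2.12. A difference in biopsy site was not separated from the fall of MEP1B. In all, 108 of 15978 genes passed (0.676%), 56 higher and 52 lower in CD.

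Of the other genes with the largest rises, GPX8 (1.76 ± 0.32, SE) and FKBP11 (1.51 ± 0.30) belong to the endoplasmic reticulum, and TUSC3 (1.502 ± 0.33) is part of the enzyme that adds sugars to new proteins there. APCDD1, an inhibitor of Wnt signals, rose by 1.49 ± 0.33, PSAT1, an enzyme of serine synthesis, by 1.38 ± 0.31, and NUCB2, a calcium-binding protein, by 1.27 ± 0.25 (SE). Their adjusted p lay between 0.0165 and 0.0376, and at least 10 of 11 CD samples lay above the REF mean for each. Lower in CD were the detoxifying enzyme GSTA1 (-2.05 ± 0.50, SE), the vitamin C transporter SLC23A1 (-1.66 ± 0.39) and its relative SLC23A3 (-1.77 ± 0.33). So were the keratin KRT12 (-1.90 ± 0.38), PRAP1 (-1.78 ± 0.37) and the myosin light chain MYL5 (-1.18 ± 0.26), with adjusted p from 0.0183 to 0.0447 and at least 10 of 11 samples below the REF mean.

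Of 18 measured genes of the unfolded protein response, 2 rose (8 adjusted over the list alone), the transcription factor XBP1 (0.93 ± 0.21, SE) and EDEM1 (0.42 ± 0.10), which helps clear misfolded proteins. The list lay at a median of 0.36, or 0.46 with clusters as a block (camera adjusted p = 1.94e-07, adjusted p = 0.294 with an estimated correlation). XBP1 is also a plasma cell gene, and 2 of 23 B cell and plasma cell markers rose (8 higher and 1 lower adjusted over the list alone), XBP1 and PRDM1 (0.79 ± 0.18). That list had a median of 0.46, or 0.36 with clusters as a block (camera adjusted p = 1.65e-05, adjusted p = 0.294 with an estimated correlation). Of 24 chemokines, CXCL1 alone passed over all genes and 12 were higher adjusted over the list alone. Their median was 1.15, or 0.94 with clusters as a block (camera adjusted p = 1.63e-08, adjusted p = 0.294 with an estimated correlation), and CXCL9, which attracts T cells, stood at 2.68 ± 0.72 (SE, adjusted p = 0.0569). Of 23 genes of epithelial antimicrobial defence, DUOX2 passed (6 higher adjusted over the list alone), and REG1A stood at 3.08 ± 1.08 (SE, adjusted p = 0.103). The median was 1.18, or 1.47 with clusters as a block (camera adjusted p = 1.46e-06, adjusted p = 0.294 with an estimated correlation).

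Several inflammatory lists had 0 genes past limma's threshold over all genes, where 3825 of 15978 genes had an unadjusted p under 0.05. Collagens and extracellular matrix had a median of 0.75, or 0.78 with clusters as a block, with 15 of 22 higher adjusted over the list alone (camera adjusted p = 7.35e-10, adjusted p = 0.294 with an estimated correlation), and LUM, a matrix proteoglycan, stood at 1.68 ± 0.58 (SE). Monocyte and macrophage markers had a median of 0.91, or 0.78 with clusters as a block, with 11 of 16 higher adjusted over the list alone (camera adjusted p = 9.93e-07, adjusted p = 0.294 with an estimated correlation). The interferon-gamma response had a median of 0.59, or 0.54 with clusters as a block, with 9 of 16 higher adjusted over the list alone (camera adjusted p = 6.59e-08, adjusted p = 0.294 with an estimated correlation), with IDO1 at 2.19 ± 0.69 (SE) and GBP5 at 2.0 ± 0.59. Matrix proteases had a median of 1.08, or 0.96 with clusters as a block, with 7 of 15 higher adjusted over the list alone (camera adjusted p = 0.000197, adjusted p = 0.294 with an estimated correlation), and MMP3, stromelysin, stood at 3.43 ± 0.97 (SE, adjusted p = 0.0622).

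T cell markers had a median of 0.48, or 0.24 with clusters as a block, and 0 of 22 passed over all genes or over the list alone (camera adjusted p = 0.000116, adjusted p = 0.30 with an estimated correlation). Neutrophil markers had a median of 1.17, or 1.18 with clusters as a block, with 3 of 18 higher adjusted over the list alone (camera adjusted p = 1.60e-05, adjusted p = 0.30 with an estimated correlation), and MNDA stood at 2.15 ± 0.66 (SE, adjusted p = 0.0772).

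Of 26 genes of xenobiotic, steroid and lipid metabolism 1 fell, the export pump ABCC3 (-0.93, adjusted p = 0.0398), named after its value was seen, and 14 were lower adjusted over the list alone. The list's median was -0.75, or -0.80 with clusters as a block (camera adjusted p = 1.46e-06, adjusted p = 0.294 with an estimated correlation), with the drug efflux pump ABCG2 at -2.25 ± 0.64 (SE, adjusted p = 0.0632). Butyrate uptake and fatty acid oxidation had a median of -0.42, or -0.37 with clusters as a block, and 9 of 20 genes lower adjusted over the list alone (camera adjusted p = 7.29e-06, adjusted p = 0.30 with an estimated correlation), with the butyrate transporter SLC16A1 at -1.29 ± 0.40 (SE). Mature colonocyte genes had a median of -0.61, or -0.73 with clusters as a block, where 1 of 24 lay above 0. None passed over all genes or over the list alone (camera adjusted p = 0.00228, adjusted p = 0.440 with an estimated correlation). Of 9 distal colon genes 0 passed. Their median was 0.42, or 0.33 with clusters as a block (camera adjusted p = 0.0349, adjusted p = 0.294 with an estimated correlation). Of 12 proximal colon genes 0 passed (1 lower adjusted over the list alone). Their median was -0.32 in both fits (camera adjusted p = 0.0198, adjusted p = 0.334 with an estimated correlation).

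IL6 and genes of its pathway are given whatever their values. IL6 did not pass in CD, at 1.09 ± 0.55 (SE, adjusted p = 0.220). CD replicate 2 had an IL6 log2 ratio of 5.85, the next highest CD sample had 1.43, and without CD replicate 2 the value for IL6, CD against REF was 0.60. STAT3, which carries the IL-6 signal to the nucleus, stood at 0.32 ± 0.11 (SE, adjusted p = 0.0926, 10 of 11 samples). Its inhibitor SOCS3 stood at 0.29 ± 0.24 (adjusted p = 0.445), the receptor IL6R at -0.17 ± 0.12 (adjusted p = 0.353), the co-receptor IL6ST at 0.49 ± 0.32 (adjusted p = 0.331) and IL17A at 0.13 ± 0.13 (adjusted p = 0.529). Of the 26 genes of the pathway 0 passed, with 3 higher and 1 lower adjusted over the list alone. The median was 0.26, or 0.28 with clusters as a block (camera adjusted p = 0.00117, adjusted p = 0.30 with an estimated correlation).

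With clusters as a block the count for CD fell from 108 to 4 genes (3601 at an unadjusted p under 0.05), and 108 of the 108 had the pooled direction. In cluster 1 alone (7 CD, 5 REF) limma called 0 genes (1859 at an unadjusted p under 0.05), with DUOX2 at 3.68 and MEP1B at -2.87. DUOX2 was 3.40 ± 0.85 (SE, adjusted p = 0.0621), CXCL1 2.90 ± 0.73 (SE, adjusted p = 0.0621) and MEP1B -2.76 ± 0.58 (SE, adjusted p = 0.0502) with clusters as a block, and without CD replicate 2 the adjusted p of CXCL1, CD against REF, was 0.0511. The count moved between 0 (without REF replicate 4) and 1695 (without CD replicate 9) when 1 sample was left out.

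**Figure D2:**
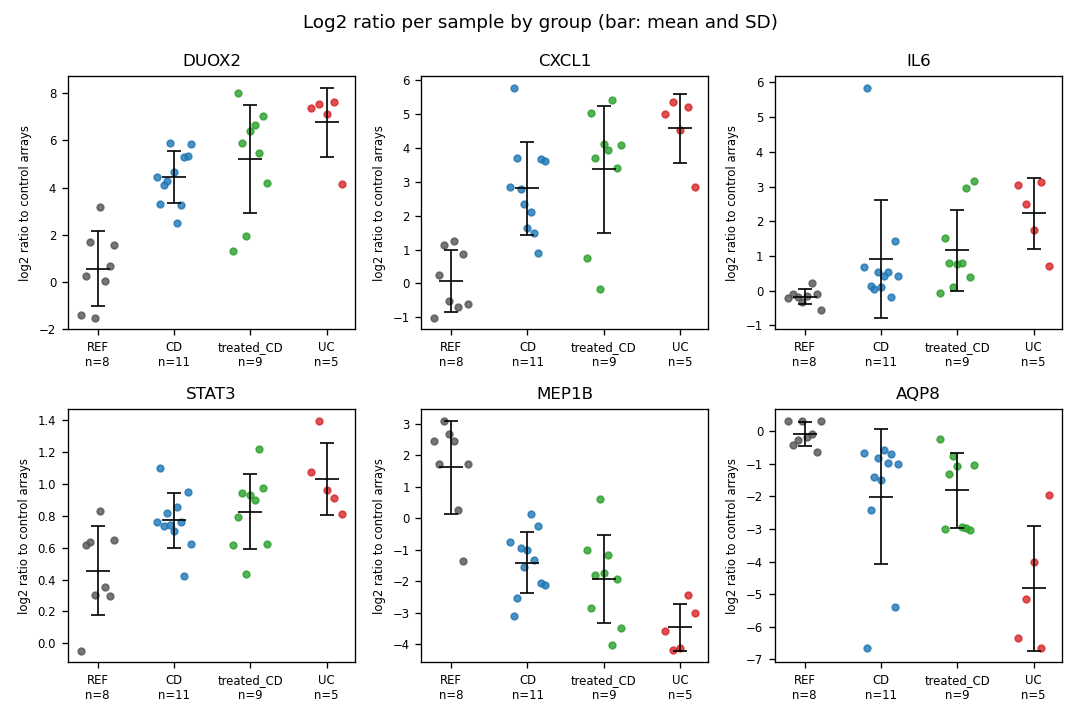
Log2 ratio to the control arrays (vertical axis) of DUOX2, CXCL1, IL6, STAT3, MEP1B and AQP8 by group (horizontal axis), with 1 point per sample and bars for the mean and SD (8 REF, 11 CD, 9 treated CD and 5 UC samples). DUOX2 has means of 0.56 in REF, 4.45 in CD, 5.21 in treated CD and 6.76 in UC, and in IL6 a single CD sample stands at 5.85.

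UC at diagnosis was compared with REF, and the differences were larger. SLC6A14, an amino acid transporter of inflamed epithelium, rose 80.0-fold, from -0.44 ± 0.43 (SD, n = 8) to 5.88 ± 3.09 (SD, n = 5), a log2 difference of 6.32 ± 1.10 (SE, adjusted p = 7.08e-05). UC replicate 5 stood at 0.40 and the next lowest UC sample at 6.87, so this 1 sample lowered the mean and the fold. DUOX2 rose by 6.20 ± 0.91 (SE, adjusted p = 1.66e-05), and the matrix proteases MMP1 and MMP3 rose by 6.03 ± 1.16 and 5.91 ± 1.19 (SE, adjusted p = 0.000177 and 0.000265). The water channel AQP8 stood at -4.75 ± 0.84 (SE, adjusted p = 8.52e-05), the gluconeogenic enzyme PCK1 at -4.83 ± 0.91 (adjusted p = 0.000147) and MEP1B at -5.09 ± 0.66 (adjusted p = 6.22e-06). KRT12 fell by 3.64 (adjusted p = 5.15e-06). All 5 UC samples lay beyond the REF mean for each of these genes. In all, 8599 of 15978 genes passed (53.8%), 3223 higher and 5376 lower, while the median of all genes lay at -0.12, so that with each array centred on its median 4383 genes were higher and 3578 lower.

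Inflammatory genes rose across most lists. No cluster held both UC and REF, so values with clusters as a block run indirectly through CD. Of 24 chemokines 20 rose (21 adjusted over the list alone), among them the neutrophil attractants CXCL6 (5.17 ± 0.99, SE), CXCL5 (4.95 ± 1.04) and CXCL1 (4.495 ± 0.76). Their median was 2.62, or 1.33 with clusters as a block (camera adjusted p = 4.13e-08, adjusted p = 0.353 with an estimated correlation). Of 15 matrix proteases and inhibitors 11 rose (11 adjusted over the list alone), with MMP10 at 5.35 ± 0.99 (SE) and the macrophage elastase MMP12 at 5.17 ± 0.95. The median was 2.86, or 2.57 with clusters as a block (camera adjusted p = 7.17e-06, adjusted p = 0.353 with an estimated correlation). Of 22 collagens and matrix genes 20 rose (21 adjusted over the list alone), with LUM at 3.75 ± 0.72 (SE) and COL6A3 at 2.93 ± 0.45. The median was 1.99, or 1.43 with clusters as a block (camera adjusted p = 1.08e-10, adjusted p = 0.353 with an estimated correlation). Of 23 antimicrobial genes 14 rose and 1 fell (14 and 1 adjusted over the list alone), with REG1A at 5.08 ± 1.32 (SE). The median was 2.43, or 2.79 with clusters as a block (camera adjusted p = 5.31e-06, adjusted p = 0.353 with an estimated correlation). The member that fell was OLFM4 (-3.60 ± 0.98, SE, adjusted p = 0.00334), which turned to 2.18 with clusters as a block.

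Markers of other cells moved with these lists. Neutrophil markers rose in 12 of 18 (13 adjusted over the list alone), with MNDA at 4.62 ± 0.81 (SE) and S100A8, a subunit of calprotectin, at 4.31 ± 1.21. The median was 2.36, or 2.28 with clusters as a block (camera adjusted p = 3.20e-05, adjusted p = 0.404 with an estimated correlation). T cell markers rose in 16 of 22 (18 adjusted over the list alone), with TRAT1 at 3.56 ± 0.70 (SE) and GZMK at 2.68 ± 0.62. The median was 1.25, or 0.34 with clusters as a block (camera adjusted p = 4.39e-07, adjusted p = 0.353 with an estimated correlation). B cell and plasma cell markers rose in 12 of 23 and 1 fell, PAX5, named after its value was seen (-0.68, adjusted over the list alone 12 and 1). The plasma cell genes TNFRSF17 (3.13 ± 0.63, SE) and MZB1 (2.55 ± 0.43) led. The median was 1.51, or 0.70 with clusters as a block (camera adjusted p = 4.67e-06, adjusted p = 0.353 with an estimated correlation). Monocyte and macrophage markers rose in 12 of 16 (12 adjusted over the list alone), with FCER1G at 3.34 ± 0.68 (SE) and CD163 at 2.97 ± 0.76. The median was 1.84, or 0.64 with clusters as a block (camera adjusted p = 6.32e-05, adjusted p = 0.404 with an estimated correlation).

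Smaller lists were mixed. Of 11 mast cell and eosinophil markers 5 rose and 1 fell (5 and 1 adjusted over the list alone), with CPA3, a protease of mast cells, at 5.09 ± 0.97 (SE) and KIT at 2.93 ± 0.55. The member that fell was SIGLEC8 (-0.27), named after its value was seen. The median of 1.12 became 0.28 with clusters as a block (camera adjusted p = 0.00257, adjusted p = 0.353 with an estimated correlation). Of 19 endothelial markers 12 rose (13 adjusted over the list alone), with VCAM1 at 2.99 ± 0.71 and PECAM1 at 1.94 ± 0.37 (SE). The median was 0.82, or 0.49 with clusters as a block (camera adjusted p = 3.87e-05, adjusted p = 0.404 with an estimated correlation). Of 16 smooth muscle, fibroblast and glial markers 7 rose and 3 fell (7 and 3 adjusted over the list alone), with the fibroblast gene PDPN at 2.16 ± 0.48 (SE). The median of 0.18 became 0.77 with clusters as a block (camera adjusted p = 0.177). Of 16 goblet cell markers 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.258), with SPINK4 at 3.37 ± 0.77 and ZG16 at -2.02 ± 0.72 (SE). Of 15 enteroendocrine markers 3 rose (2 adjusted over the list alone), with the prohormone convertase PCSK1 at 3.93 ± 0.71 (SE). The median of 0.92 became 0.039 with clusters as a block (camera adjusted p = 0.0133, adjusted p = 0.486 with an estimated correlation). Of 12 blood transcripts 4 rose, with haemoglobin beta, HBB, at 3.76 ± 0.66 (SE), or 1.25 with clusters as a block, and 5 fell, with CA1, also a colonocyte enzyme, at -2.96 ± 0.79 (4 and 5 adjusted over the list alone, camera adjusted p = 0.778).

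Metabolic genes of the epithelium fell. Of 20 genes of butyrate uptake and fatty acid oxidation 17 fell (17 adjusted over the list alone), with the dehydrogenase ACADS at -2.09 ± 0.34 (SE) and SLC16A1 at -1.83 ± 0.50. The median was -1.06, or -0.99 with clusters as a block (camera adjusted p = 1.01e-05, adjusted p = 0.404 with an estimated correlation). Of 26 respiratory chain genes 23 fell (24 adjusted over the list alone), with UQCRC1 at -1.54 ± 0.30 (SE). The median was -0.49, or -0.38 with clusters as a block (camera adjusted p = 3.09e-05, adjusted p = 0.453 with an estimated correlation). Of 26 genes of xenobiotic, steroid and lipid metabolism 19 fell and 1 rose (20 and 1 adjusted over the list alone), with the steroid enzyme HSD3B2 at -5.73 ± 1.38 (SE). The median was -1.48, or -1.67 with clusters as a block (camera adjusted p = 0.000592, adjusted p = 0.445 with an estimated correlation), and the member that rose was ABCB4 (1.41), named after its value was seen. Of 24 mature colonocyte genes 13 fell (13 adjusted over the list alone), with MS4A12 at -3.85 ± 0.92 (SE) and the guanylin gene GUCA2A at -3.71 ± 0.78. The median was -1.17, or -1.89 with clusters as a block (camera adjusted p = 0.00257, adjusted p = 0.516 with an estimated correlation).

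The unfolded protein response rose in 11 of 18 genes (11 adjusted over the list alone), with the chaperones DNAJB9 at 2.22 ± 0.37 (SE) and DNAJC3 at 1.88 ± 0.25, and XBP1 at 1.83 ± 0.25. Its median was 0.67, or 1.01 with clusters as a block (camera adjusted p = 4.06e-06, adjusted p = 0.353 with an estimated correlation). IL6 rose by 2.41 ± 0.67 (SE, adjusted p = 0.00408, 5 of 5 samples), STAT3 by 0.58 ± 0.13 (adjusted p = 0.000701), IL17A by 0.53 ± 0.16 (adjusted p = 0.00607) and IL6ST by 1.64 ± 0.39 (adjusted p = 0.00117), and IL6R fell by 0.42 (adjusted p = 0.0157), as did FGL1 (-0.82), named after its value was seen. UC replicate 2 had an IL17A log2 ratio of 1.504, and the next highest UC sample had 0.60. The size of the IL17A rise thus leans on 1 sample, though 5 of 5 UC samples lay above the REF mean. SOCS3 stood at 0.57 ± 0.29 (SE, adjusted p = 0.0927). Of the 26 genes of the IL-6 pathway 10 rose and 2 fell (10 and 2 adjusted over the list alone), with the protease inhibitor TIMP1 at 3.41 ± 0.58 (SE) and OSMR, the oncostatin M receptor, at 2.19 ± 0.41. Its median was 0.34, or 0.57 with clusters as a block (camera adjusted p = 0.00132, adjusted p = 0.404 with an estimated correlation). Of 18 cytokines of the Th17, TNF and IL-1 axes 11 rose and 1 fell (11 and 1 adjusted over the list alone), with IL1B at 2.47 ± 0.71 (SE) and IL1A at 2.14 ± 0.65 rising and IL23R, named after its value was seen, falling (-0.45, 4 of 5 samples). The median was 0.54, or 0.56 with clusters as a block (camera adjusted p = 0.000379, adjusted p = 0.353 with an estimated correlation).

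Of 16 interferon-gamma response genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), with GBP5 at 2.92 ± 0.73 (SE) and CD74 at 2.25 ± 0.39 rising and CIITA, named after its value was seen, falling (-0.48). The median was 0.86, or 0.54 with clusters as a block (camera adjusted p = 0.00188, adjusted p = 0.444 with an estimated correlation). Of 18 type I interferon genes 2 rose and 3 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.778), with OASL at -2.03 ± 0.53 and IFIT1 at -1.83 ± 0.36 (SE). OAS2 (1.24) and IFI6 (1.07) rose, and XAF1, named after its value was seen, fell (-0.95) but stood at 0.15 with clusters as a block. Of 25 proliferation genes CDC20 fell (-0.81 ± 0.32, SE, adjusted p = 0.0313) and 0 passed adjusted over the list alone. The proliferation median was -0.038 (camera adjusted p = 0.836), but 0.57 with clusters as a block, where 25 of 25 genes lay above 0 (camera adjusted p = 2.40e-06, adjusted p = 0.357 with an estimated correlation). The block value runs through CD, so 0.57 is no direct estimate for UC. In CD the proliferation median went from 0.20 to 0.41 with clusters as a block, with 25 of 25 genes above 0. Of 20 glucocorticoid-responsive genes 3 rose and 4 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.477), with ANXA1 at 3.43 ± 0.48 (SE), and of 18 immediate early genes 5 rose (5 adjusted over the list alone), with the matrix signal CCN1 at 4.30 ± 0.76 (SE, camera adjusted p = 0.0225, adjusted p = 0.516 with an estimated correlation).

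Of the lists of colon position, camera called the proximal but not the distal one. Over all 15978 genes 3223 rose and 5376 fell in UC, which is the background for the counts here. Of 12 genes of the proximal colon 8 fell (8 adjusted over the list alone), with HOXB6 at -2.10 ± 0.34 and ETNK1 at -2.14 ± 0.58 (SE). The median was -0.67, or -0.80 with clusters as a block (camera adjusted p = 0.0401, adjusted p = 0.453 with an estimated correlation). Of 9 distal genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.326), HOXD10 by 1.14 ± 0.32 (SE), or 0.20 with clusters as a block, and HOXD11 by 0.83. Of 14 ileal enterocyte and Paneth markers 5 fell (4 adjusted over the list alone, camera adjusted p = 0.439), with ANPEP at -3.53 ± 0.71 and the bile acid transporter SLC10A2 at -2.06 ± 0.35 (SE), the latter -0.38 with clusters as a block. Of 14 housekeeping genes 4 rose and 2 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.388), with TBP at -0.64 ± 0.14 (SE).

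With clusters as a block limma called 0 genes between UC and REF (3007 at an unadjusted p under 0.05), and no cluster held both groups, so UC and cluster cannot be told apart for most genes. Of the 8599 genes 8050 (93.6%) had the pooled direction with clusters as a block, with DUOX2 at 5.15 ± 1.503, SLC6A14 at 7.17 ± 1.80 and MEP1B at -5.24 ± 1.03 (SE), whereas CDC20 turned from -0.81 to 0.51. In that fit IL6 was 3.01, but TRAT1 was 0.19, IL6ST 0.16, CD163 0.80 and VCAM1 0.60.

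**Figure D3:**
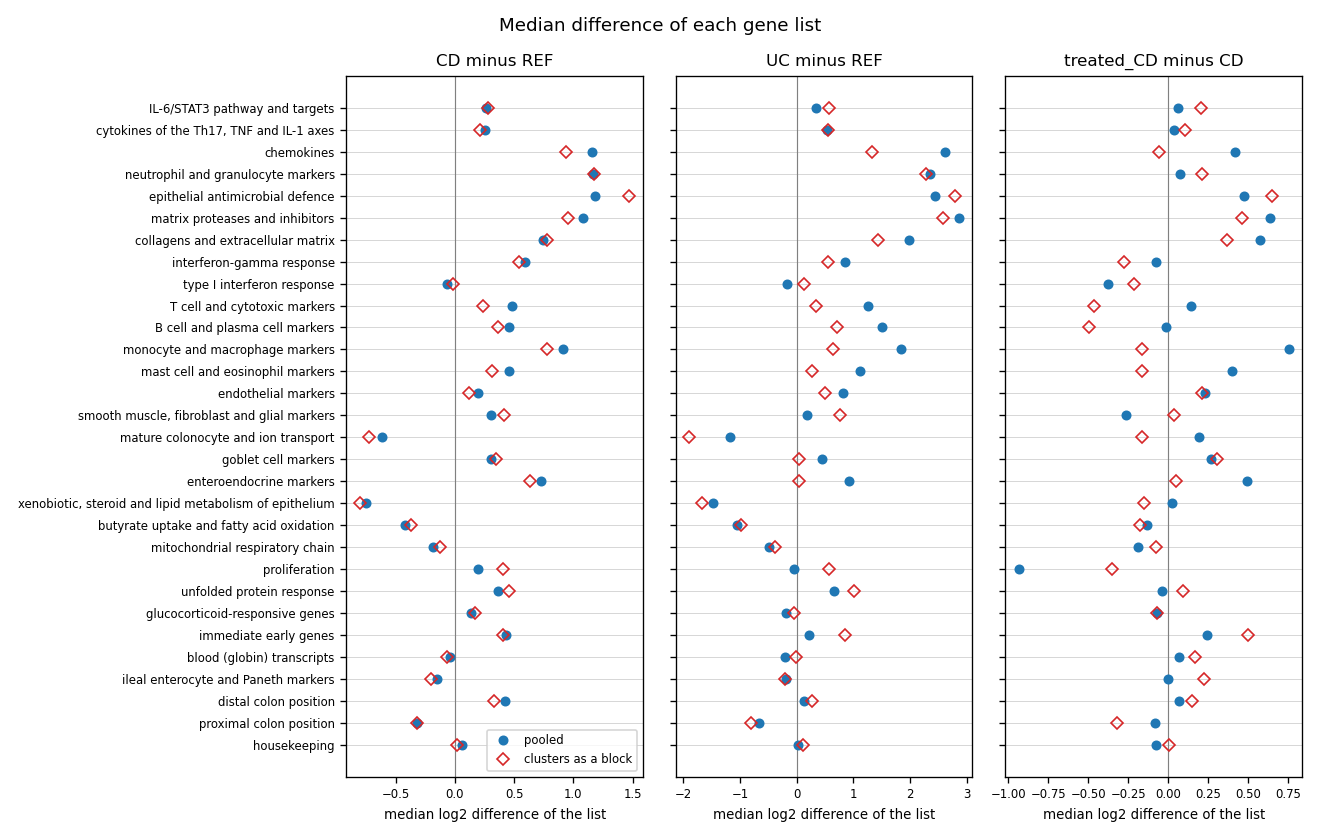
Median log2 difference of each gene list (horizontal axis, log2) for CD minus REF, UC minus REF and treated CD minus CD, 1 line per list, with filled circles for the pooled fit and open diamonds for clusters as a block. The chemokine median is 1.15 and 2.62 in the pooled fit of CD and UC against REF, and the proliferation median of treated CD minus CD moves from -0.93 to -0.35 with clusters as a block.

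CD and UC were compared with each other to find what separates the 2 diseases at diagnosis, which is also the test of whether their differences from REF differ. PCK1 was 11.8-fold higher in CD, at -1.62 ± 1.93 (SD, n = 11) against -5.19 ± 1.81 (SD, n = 5), a log2 difference of 3.57 ± 0.86 (SE, adjusted p = 0.00875, 10 of 11 samples). AQP8 (2.82 ± 0.80, SE, adjusted p = 0.0164), the guanylins GUCA2A (2.47 ± 0.74) and GUCA2B (2.16 ± 0.65), the creatine kinase CKB (2.52 ± 0.59) and the laminin LAMA1 (2.57 ± 0.49) were also higher in CD, as was MS4A12 (2.76 ± 0.87). MMP10 (-3.62 ± 0.93, SE), MMP1 (-3.42 ± 1.10), SLC6A14 (-3.25 ± 1.04), GREM1 (-3.10 ± 0.90), an inhibitor of BMP signals, and TCN1 (-2.94 ± 0.76), a vitamin B12 binder, were lower in CD, with adjusted p from 0.0112 to 0.0274. So were MMP12 (-3.07 ± 0.90, SE), CH25H (-3.02 ± 0.57) and MMP7 (-2.98 ± 1.04). In all, 3862 of 15978 genes (24.2%) differed, 2526 higher and 1336 lower in CD, or 1358 and 1864 with arrays centred on their median.

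By list, 12 of 22 collagens and matrix genes were lower in CD (16 adjusted over the list alone), with COL6A3 at -1.68 ± 0.43 and LUM at -2.07 ± 0.68 (SE). The median was -1.09, or -0.66 with clusters as a block (camera adjusted p = 1.35e-08, adjusted p = 0.549 with an estimated correlation). Of 15 matrix proteases 7 were lower (9 adjusted over the list alone). The median was -1.73, or -0.95 with clusters as a block (camera adjusted p = 1.22e-05, adjusted p = 0.549 with an estimated correlation). T cell markers were lower in 10 of 22 (12 adjusted over the list alone), with GZMA at -1.74 ± 0.46 and TRAT1 at -2.51 ± 0.67 (SE), but TRAT1 turned to 0.11 and the list's median went from -0.92 to -0.11 with clusters as a block (camera adjusted p = 4.93e-07, adjusted p = 0.549 with an estimated correlation). Of 26 respiratory chain genes 15 were higher in CD (18 adjusted over the list alone), with UQCRC1 at 1.15 ± 0.28 (SE). The median was 0.31, or 0.24 with clusters as a block (camera adjusted p = 2.21e-05, adjusted p = 0.601 with an estimated correlation). Of 20 genes of butyrate uptake and fatty acid oxidation 9 were higher (11 adjusted over the list alone), with ACADS at 1.25 ± 0.32 (SE). The median was 0.56, or 0.52 with clusters as a block (camera adjusted p = 0.000171, adjusted p = 0.601 with an estimated correlation). Of 18 genes of the unfolded protein response 6 were lower (6 adjusted over the list alone), with DNAJC3 at -1.45 ± 0.24 and XBP1 at -0.91 ± 0.24 (SE). The median was -0.28, or -0.50 with clusters as a block (camera adjusted p = 0.000171, adjusted p = 0.549 with an estimated correlation).

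With clusters as a block limma called 0 genes between CD and UC (908 at an unadjusted p under 0.05), and 3501 of the 3862 (90.6%) had the pooled direction. PCK1 was 3.98, MMP10 -3.45, MMP12 -0.92 and CH25H -0.70 with clusters as a block. OLFM4, at 3.56 ± 0.93 (SE) in the pooled fit, turned to -0.33 with clusters as a block, and quantile normalisation left 1 gene of CD against UC past the threshold. The count moved between 964 (without UC replicate 4) and 4795 (without CD replicate 1) when 1 sample was left out, and was 1842 without UC replicate 3 and 1984 without UC replicate 2.

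CD during therapy was compared with CD at diagnosis to see what changed under treatment, without a label on which drug was given. Genes of cell division fell. Of 25 proliferation genes 22 fell (24 adjusted over the list alone), with the mitotic genes AURKB at -1.4 ± 0.24 (SE), CDC20 at -1.26 ± 0.25 and MKI67 at -1.15 ± 0.22 and the nucleotide enzyme RRM2 at -1.26 ± 0.31, and all 9 treated samples lay below the CD mean for each. The median was -0.93 (camera adjusted p = 6.09e-16, adjusted p = 0.807 with an estimated correlation) and -0.35 with clusters as a block. The difference in the list's mean score was -0.51 within cluster 3 (5 treated, 1 CD) and -0.25 within cluster 4 (4 treated, 2 CD), against -0.88 pooled. In all, 1485 of 15978 genes passed (9.29%), 467 higher and 1018 lower in treated CD, or 567 and 639 with arrays centred on their median.

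The replication factor GINS2 (-1.32 ± 0.26, SE), the cell cycle regulator FOXM1 (-1.31 ± 0.25), the histone H4C8 (-1.51 ± 0.34), ARSL (-1.83 ± 0.44), PYROXD1 (-2.15 ± 0.51) and NLRP2 (-1.37 ± 0.44) were among the largest decreases, and OLFM4 fell from 5.24 ± 2.57 (SD, n = 11) to 1.55 ± 0.23 (SD, n = 9). Among the largest increases were CCL2, which attracts monocytes (2.28 ± 0.47, SE, adjusted p = 0.00563), CH25H, which makes an oxysterol (2.29 ± 0.48), the folate hydrolase FOLH1 (2.36 ± 0.77) and CCN1 (2.35 ± 0.60). They also included the transglutaminase F13A1 (2.21 ± 0.51), the IgE receptor FCER1A (2.04 ± 0.40), the macrophage scavenger receptor CD163 (2.03 ± 0.60) and HBB (2.01 ± 0.52). With clusters as a block OLFM4 turned to 0.23, ARSL to 0.11 and H4C8 to 0.16, CD163 was 0.17 and CH25H 0.35.

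Of 22 collagens and matrix genes 3 rose (5 adjusted over the list alone), DCN at 1.76 ± 0.48 (SE), LUM at 1.76 ± 0.57 and COL3A1 at 1.08. The median was 0.57, or 0.37 with clusters as a block (camera adjusted p = 2.34e-06, adjusted p = 0.807 with an estimated correlation). Of 24 chemokines CCL2, CCL11 (1.86) and CXCL12 (1.09) rose (3 adjusted over the list alone). The median of 0.42 became -0.059 with clusters as a block (camera adjusted p = 0.00476, adjusted p = 0.807 with an estimated correlation). Of 16 macrophage markers CD163 and CD14 (0.82 ± 0.26, SE) rose (3 adjusted over the list alone). The median of 0.75 became -0.16 with clusters as a block (camera adjusted p = 0.000226, adjusted p = 0.807 with an estimated correlation). Of 11 mast cell and eosinophil markers FCER1A rose (2 adjusted over the list alone), and the median of 0.40 became -0.16 with clusters as a block (camera adjusted p = 0.00637, adjusted p = 0.807 with an estimated correlation). Of 23 antimicrobial genes C3 rose (1.98) and OLFM4 fell (camera adjusted p = 0.0920), and C3 turned to -0.12 with clusters as a block. Of 16 goblet cell markers RETNLB (1.92 ± 0.41, SE) and ITLN1 (1.46 ± 0.46) rose (2 adjusted over the list alone). The median was 0.27, or 0.30 with clusters as a block (camera adjusted p = 0.00728, adjusted p = 0.807 with an estimated correlation). Of 26 genes of xenobiotic, steroid and lipid metabolism the drug efflux pump ABCB1 (1.28 ± 0.41, SE) and the drug-metabolising CYP3A4 (1.20 ± 0.27) rose (2 adjusted over the list alone, camera adjusted p = 0.101). Of 16 interferon-gamma response genes the peptide transporter TAP2 (-0.92 ± 0.25, SE) and HLA-F (-0.53 ± 0.15) fell (2 adjusted over the list alone, camera adjusted p = 0.490). Of 26 respiratory chain genes 5 fell (8 adjusted over the list alone), with UQCRC1 at -0.84 ± 0.23 and NDUFV1 at -0.67 ± 0.16 (SE). The median was -0.19, or -0.079 with clusters as a block (camera adjusted p = 0.00232, adjusted p = 0.807 with an estimated correlation). Of 26 genes of the IL-6 pathway IL6ST (1.20 ± 0.31, SE) and JAK1 (0.34) rose (1 adjusted over the list alone, camera adjusted p = 0.125), and IL6ST was 0.02 with clusters as a block.

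Between treated CD and CD limma called 0 genes with clusters as a block (283 at an unadjusted p under 0.05), and 1126 of the 1485 (75.8%) had the pooled direction. The count moved between 623 (without CD replicate 8) and 2750 (without CD replicate 1) when 1 sample was left out.

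Treated CD was compared with REF to see what remained different during therapy. DUOX2 was 25-fold higher, at 5.21 ± 2.29 (SD, n = 9) against 0.56 ± 1.59 (SD, n = 8), a log2 difference of 4.64 ± 0.78 (SE, adjusted p = 0.000118, 9 of 9 samples). SLC6A14 (4.54 ± 0.94, SE), CCN1 (4.35 ± 0.65) and CCL2 (4.15 ± 0.51, adjusted p = 2.64e-05) also rose, and MEP1B fell (-3.56 ± 0.57, SE, adjusted p = 8.51e-05). Among the largest differences were also PRAC1, at 5.02 ± 1.37 (SE), and HSD3B2, the steroid enzyme, at -4.04 ± 1.18. All REF samples lay in clusters 1 and 2 and all treated CD samples in clusters 3 and 4. Between these pairs of clusters the lowest and highest PRAC1 values shifted by 4.15 and 4.32. Those of HSD3B2 shifted by -2.41 (only a bound) and -2.07. What therapy left of these 2 differences thus cannot be told apart from the cluster. In all, 7374 of 15978 genes passed (46.2%), 2649 higher and 4725 lower, with the median of all genes at -0.10, or 3585 higher and 2975 lower with arrays centred on their median.

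Of 24 chemokines 17 rose (17 adjusted over the list alone), with CXCL1 at 3.28 ± 0.65 (SE). The median was 1.76, or 0.81 with clusters as a block (camera adjusted p = 2.84e-07, adjusted p = 0.425 with an estimated correlation). Collagens and matrix genes rose in 18 of 22 (21 adjusted over the list alone), with LUM at 3.43 ± 0.61 (SE). The median was 1.31, or 1.23 with clusters as a block (camera adjusted p = 7.48e-11, adjusted p = 0.425 with an estimated correlation). Macrophage markers rose in 12 of 16 (13 adjusted over the list alone), with CD163 at 3.59 ± 0.65 (SE). The median was 1.62, or 0.63 with clusters as a block (camera adjusted p = 2.84e-07, adjusted p = 0.425 with an estimated correlation). Goblet cell markers rose in 7 of 16 (7 adjusted over the list alone), with ITLN1 at 2.70 ± 0.50 and RETNLB at 2.59 ± 0.44 (SE), and enteroendocrine markers in 8 of 15 (8 adjusted over the list alone), with PCSK1 at 3.31 ± 0.61. Their medians were 0.63 and 1.24, or 0.66 and 0.62 with clusters as a block (camera adjusted p = 0.00232 and 0.000492, adjusted p = 0.455 for both with an estimated correlation). Fatty acid oxidation fell in 15 of 20 genes (15 adjusted over the list alone), with ACADS at -1.33 ± 0.29 (SE). The median was -0.64, or -0.53 with clusters as a block (camera adjusted p = 0.00105, adjusted p = 0.455 with an estimated correlation). Proliferation genes fell in 13 of 25 (13 adjusted over the list alone), with CDC20 at -1.32 ± 0.27 and AURKB at -1.30 ± 0.26 (SE). The median of -0.61 turned to 0.095 with clusters as a block (camera adjusted p = 0.000529, adjusted p = 0.472 with an estimated correlation).

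Between treated CD and REF limma called 0 genes with clusters as a block (1118 at an unadjusted p under 0.05), no cluster held both groups, and 6140 of the 7374 genes (83.3%) had the pooled direction. The values with clusters as a block run indirectly through CD. OLFM4 turned from -3.73 ± 0.84 (SE) to 2.08 with clusters as a block, and DUOX2 stood at 3.64 ± 1.402 and MEP1B at -3.51 ± 0.96 (SE).

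The genes changed in CD and in UC were compared, both groups being set against the same REF samples. DUOX2, CXCL1, GPX8, NUCB2 and XBP1 rose and MEP1B, KRT12 and ABCC3 fell in both. Of the 108 genes changed in CD, 106 changed in UC with the same direction, 54 higher and 52 lower, and 0 with the opposite direction. Independent lists of these sizes would share 11.3 higher and 17.5 lower genes. Lists that share REF samples are not independent, so these numbers are no baseline for the overlap. With the REF samples split by odd and even replicate number, the log2 differences of CD and UC correlated across genes at r = 0.876 and 0.661, genes not being independent replicates. CD called 0 and 34 genes and UC 5898 and 7794 in these 2 fits, of which 0 and 24 were shared.

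The mix of cells in a biopsy was compared between groups and between clusters in 15 measures. The first principal component carried 46.7% of the variance, and groups accounted for 61.3% and clusters for 66.2% of its spread (permutation p of the groups = 1e-05, the smallest that the permutations can give, adjusted p = 0.00015). The clusters were cut from these same arrays, so their share was partly fixed in advance and cannot be weighed against that of the groups. Within clusters the permutation p of the component was 0.0203 (adjusted p = 0.105). Scores of T cell, macrophage and mast cell markers differed between groups (permutation adjusted p = 0.00231, 0.0016 and 0.0016), but not past the threshold within clusters (permutation adjusted p = 0.251, 0.195 and 0.251). The score of mature colonocyte genes, such as AQP8 and GUCA2A, was the one that passed within clusters (permutation p = 0.00086, adjusted p = 0.0129).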

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

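The tests chosen only after the result was seen were the bound on the count in UC with centred arrays (the centring itself was fixed beforehand), the receptor-family genes, the chemokine score set beside the r values, the r against treated CD minus REF, the disease itself, biopsy site alone, and both tests of proliferation. Samples far from the others of their group were sought in 144 named genes and 30 lists by Dixon's test in REF, treated CD and UC. Of 522 tests 43 (8.24%) stood out, where chance flags about 1 in 20 groups, or 26.1 here. CD was not tested, having more than 10 samples.

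UC replicate 5 lay apart from the other UC samples in 8 of these, with the lowest DUOX2 (4.16), GPX8 (1.76), MMP3 (2.08), SLC6A14 (0.40) and DUOXA2 (1.41), the highest SLC16A1 (-0.62) and SLC10A2 (-1.05), and the lowest score of antimicrobial defence (1.61). In UC replicate 1 GBP5 (1.95), TNFRSF17 (2.49), PYROXD1 (-3.72) and the T cell list (0.37) lay apart. IL17A (1.504) lay apart in UC replicate 2, PRAC1 (4.57) and ANPEP (-5.36) in UC replicate 3, and RETNLB (-1.46) and the goblet cell list (-0.77) in UC replicate 4.

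In REF, replicate 2 lay apart in MS4A12 (-1.46) and SLC10A2 (1.74), replicate 5 in CXCL5 (3.64) and FOLH1 (3.11), replicate 6 in OLFM4 (1.15), and replicate 7 in HSD3B2 (-2.71), SLC51A (-4.33) and HOXD11 (-1.24). REF replicate 8 lay apart in XBP1 (-1.70), GINS2 (-0.78), RRM2 (-2.09) and the proliferation list (-0.73). In treated CD, replicate 1 lay apart in MMP12 (0.55) and RRM2 (-0.89), and replicate 2 in the epithelial genes GUCA2A (-3.66), GUCA2B (-3.42), ZG16 (-0.91) and CA1 (-3.66) and in the mature colonocyte list (-1.79). Treated CD replicate 6 lay apart in CYP3A4 (2.96), replicate 7 in IL1A (2.67), OAS2 (2.56), the cytokine list (1.19) and the type I interferon list (1.45), and replicate 9 in the glucocorticoid list (1.23) and the immediate early list (2.47).

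The difference from REF differed between CD and UC in 3862 genes by a test of CD against UC. Probe sets without a gene symbol entered only the fits of probe sets: of 5678, 126 changed between CD and REF (54 higher, 72 lower, 2.22%, against 1.64% of named probe sets and 0.676% of genes) and 3090 between UC and REF (629 higher, 2461 lower, 54.4%, against 53.9% and 53.8%).

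For UC against REF, a random division of the samples was argued against. The real grouping called 8599 genes and the highest of 99 others 7393 (1 of 100 splits as large, the real one, the smallest share that 100 splits can give). A random division was argued against too for CD against UC (3862, highest other 355, 1 of 100), treated CD against CD (1485, highest other 263, 1 of 100) and treated CD against REF (7374, highest other 2943, 1 of 100). The splits ignored the clusters, which are tied to the groups, so they cannot tell disease or therapy from cluster. For CD against REF a random division was not argued against: 6 of 100 splits called at least the 108 genes of the real one, and the highest other called 3046, several times the real count, which points to a structure of the samples.

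About 53.8% of all genes differed between UC and REF. A scaling of whole arrays was argued against as the whole cause, since 7961 genes passed with each array centred on its median. A divisor that differs between sample clusters stays open as a cause. Over 102 genes of olfactory, taste and vomeronasal receptors and keratin-associated proteins, which have little known function in colon, the 3 CD samples of clusters 3 and 4 minus the 8 of clusters 1 and 2 correlated with UC minus REF across genes at r = 0.669 (rank 3 of 165 splits of the CD samples, highest other 0.680). Over the splits this r followed the difference in chemokine score at 0.626, and beyond that trend the real split ranked 7 of 165. Over all genes the same r was 0.612, rank 15 of 165 (highest other 0.745), which met the bound, written before this r was computed, for counting it against a divisor. That bound was set aside after the result was seen, because over the splits r followed the difference in chemokine score (r = 0.927) and all 14 higher splits had a higher chemokine score, so that a rank below the top does not exclude a divisor. Whether that score follows disease activity or the cluster was not tested. Beyond that trend the real split ranked 39 of 165, which met the bound too. Set against treated CD minus REF, the same CD difference gave r = 0.735 over all genes (rank 4 of 165, and 20 beyond the chemokine score) and 0.696 over the receptor-family genes (rank 1, and 7 beyond it). The clusters were cut from correlations between these same samples, which placed the 3 CD samples with treated CD and UC. High r values of the real split were thus partly fixed in advance, so these ranks do not count for a divisor. Of the 102 receptor-family genes 1 rose and 56 fell in UC against REF (55.9%, against 53.8% of all genes). In treated CD against REF 0 rose and 50 fell (49.0%, against 46.2%). Calls against REF were thus about as frequent in these genes as in all genes for UC and treated CD. The shares were 22.55% against 24.2% in CD against UC, 3.92% against 9.29% in treated CD against CD, and 0% against 0.676% in CD against REF. The disease itself and the cluster cannot be told apart for most genes, because limma called 0 genes with clusters as a block (3007 at an unadjusted p under 0.05) and no cluster held both UC and REF.

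HSD3B2, PRAC1 and OLFM4 lay among the largest differences between groups. The site of the biopsy alone was argued against: the lowest PRAC1 value shifted by 4.15 log2 from clusters 1 and 2 to clusters 3 and 4 and the highest by 4.32, whereas a changed mix of sites within one range of values keeps its ends. HSD3B2 shifted by -2.07 at its upper end, while at its lower end the shift of -2.41 is only a bound, because its lowest value in clusters 3 and 4 is the lowest of the file. OLFM4 shifted only at its upper end (0.00 and -5.80). Within CD at diagnosis OLFM4 was 1.20 to 1.59 in the 3 samples of clusters 3 and 4, and 5.84 to 7.71 in the 8 of clusters 1 and 2. These values argue against the disease group alone as the cause of the OLFM4 shift. In clusters 1 and 2 the lowest PRAC1 value was -4.50 in REF and -4.63 in CD, so the lower end did not rise with CD there. The same 3 CD samples had PRAC1 of -0.21 to -0.11, above that lower end but within the range of the 8 (-4.63 to 2.87). For HSD3B2 and PRAC1 a divisor that differs between sample clusters and the disease cannot be told apart here. At both ends 45 genes shifted by over 2 log2, against at most 2 in 99 random splits. The clusters were cut from these same arrays, which favours the real split, so the random splits are no baseline. Besides, all UC and no REF samples lie in clusters 3 and 4, and DUOX2, which rose with disease, also shifted at both ends (2.84 and 2.17). Site remains open as a part of the differences, as no sample's site is given in the sources used here.

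Proliferation genes were lower in treated CD than in CD, with a score of -0.88. A divisor or batch that differs between sample clusters may be a part of this, since the CD samples of clusters 3 and 4 lay at -0.71 from those of clusters 1 and 2 (rank 2 of 165 splits, lowest other -0.74), without therapy. Therapy stays open as well: within clusters 3 and 4 treated CD minus CD was -0.38 (9 treated, 3 CD samples), with an exact permutation p of 0.0556 over 90 arrangements (two-sided).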

How the results depend on the processing

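The alternatives chosen only after seeing the data were the clusters as a block, the pairs of clusters (1 with 2, 3 with 4) as a block, cluster 1 alone, leaving out the 4 arrays of widest ratio spread, and clusters as a block with an estimated correlation. Every reversed value below comes from these. The cause of the changes was not tested unless stated.

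The 108 genes of CD against REF became 678 with quantile normalisation, 461 with probe sets in place of genes (1.76% of 26121 probe sets, against 0.676% of genes), 172 without the 40% of genes of lowest interquartile range, 58 at a fold of at least 1.5, 273 with array weights, 10 with only the 2 groups compared, 4 with clusters as a block, 26 with pairs of clusters as a block, 19 without the 4 widest arrays (REF replicates 7 and 8, CD replicates 2 and 9) and 0 by limma in cluster 1 alone (1859 at an unadjusted p under 0.05). Leaving out 1 sample gave 0 to 1695 genes: 8 without REF replicate 1, 818 without REF 2, 0 without REF 4, 362 without REF 5, 38 without REF 7, 6 without REF 8, 16 without CD replicate 1, 32 without CD 2, 20 without CD 3, 43 without CD 4, 6 without CD 5, 17 without CD 6, 278 without CD 7, 502 without CD 8, 1695 without CD 9, 8 without CD 10, 62 without CD 11, and 189 without treated CD replicate 7.

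For UC against REF (8599) the count became 14107 with probe sets (54.0% of them, against 53.8% of genes), 4301 at a fold of at least 1.5, 0 by limma with clusters as a block (3007 at an unadjusted p under 0.05) and 118 with pairs of clusters as a block, and 7261 to 9112 with 1 sample left out. For CD against UC (3862) it became 1 with quantile normalisation, 6412 with probe sets (24.6%, against 24.2% of genes), 1604 at a fold of at least 1.5, 7877 with array weights, 2217 with only the 2 groups, 0 with the replicate number as a block, and 0 with clusters (908 at an unadjusted p under 0.05) or their pairs as a block. Leaving out 1 sample gave 964 to 4795, with 1984 without UC replicate 2, 1842 without UC 3 and 964 without UC 4.

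For treated CD against CD (1485) the count became 2286 with probe sets (8.75%, against 9.29% of genes), 548 at a fold of at least 1.5, 4407 with array weights, 308 with the replicate number as a block, and 0 with clusters (283 at an unadjusted p under 0.05) or their pairs as a block. Leaving out 1 sample gave 623 to 2750: 2750 without CD replicate 1, 851 without CD 3, 890 without CD 4, 2613 without CD 5, 2461 without CD 6, 623 without CD 8, 787 without CD 9, 789 without CD 10, 985 without CD 11, 852 without treated CD replicate 2, 936 without treated CD 5, 784 without treated CD 6 and 879 without treated CD 9. CD 1, 5 and 6 are the CD samples of clusters 3 and 4. For treated CD against REF (7374) it became 12160 with probe sets (46.6%, against 46.2% of genes), 2734 at a fold of at least 1.5, and 0 with clusters (1118 at an unadjusted p under 0.05) or their pairs as a block, and 6151 to 8175 with 1 sample left out. The 106 genes shared by CD and UC became 56 at a fold of at least 1.5, 645 with quantile normalisation and 17 with pairs of clusters as a block.

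With clusters as a block, then with their pairs, OLFM4 turned to 2.18 and 1.78 in UC against REF, -0.33 and -0.35 in CD against UC, 0.23 and 0.22 in treated CD against CD, and 2.08 and 1.65 in treated CD against REF. CDC20 turned to 0.51 and 0.52 in UC against REF and 0.063 and 0.012 in treated CD against REF. In treated CD against CD ARSL turned to 0.11 and 0.082, H4C8 to 0.16 and 0.13, and C3 to -0.12 and -0.16. With clusters alone TRAT1 turned to 0.11 in CD against UC and XAF1 to 0.15 in UC against REF. With pairs alone IL6ST turned to -0.064 in UC against REF and -0.043 in treated CD against CD, ABCB4 to -0.14 in UC against REF and CXCL12 to -0.043 in treated CD against CD. Lists called in at least 1 of the fits, whose camera direction turned with clusters as a block, had medians there as follows: macrophages in CD against UC (0.19), and chemokines (-0.059), T cells (-0.47), B cells (-0.49, from -0.011), macrophages (-0.16), mast cells (-0.16) and glucocorticoid-responsive genes (-0.070 in both fits) in treated CD against CD, and T cells (-0.17) and proliferation (0.095) in treated CD against REF. Of 150 list medians 27 changed sign in that fit, among them proliferation in UC against REF (-0.038 to 0.57) and in CD against UC (0.33 to -0.15), enteroendocrine markers (-0.29 to 0.45) and immediate early genes (0.088 to -0.52) in CD against UC, and mature colonocyte genes in treated CD against CD (0.19 to -0.16).

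Of 222 gene results, 193 lost their call with clusters as a block, 173 with their pairs, 63 with the replicate number as a block, 43 with quantile normalisation and 9 with centred arrays, and 0 changed with the most variable probe set per gene. Of 150 list results 93 lost their call with the estimated correlation and 51 with fry. Whether the replicate numbers pair the samples stays open. Samples sharing a number correlated best with each other in 0 to 2 cases per comparison. In treated CD against CD their median r was 0.090, against 0.0055 over all pairs, and 4 of 9 were over 0.1. Clusters separate most CD samples from treated CD, so this check cannot exclude shared donors. A covariate for RNA quality was not run, as the files hold no control probe sets for it.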

Other observations

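The tests of pairs of clusters as a block, of clusters as a block, of the covariance with disjoint REF samples, of the receptor-family genes, of the chemokine score and of r against treated CD minus REF were chosen only after the result was seen. Beyond the genes named by rule, the genes that passed between UC and REF with pairs of clusters as a block, numbered 118 (72 higher, 46 lower). That contrast is indirect, since no pair of clusters held both UC and REF, and runs through CD (8 samples in clusters 1 and 2, 3 in clusters 3 and 4). With all 4 clusters as a block 0 genes passed between UC and REF (lowest adjusted p = 0.0555). Those named here were picked after their values were seen. Higher in UC were the amino acid transporter SLC6A14 (7.71, adjusted p = 0.0367), CXCL1 (5.23), the DUOX2 partner DUOXA2 (4.39), the brake on NF-kappa-B signals TNIP3 (4.30), the complement regulator C4BPB (3.67), the nitric oxide synthase NOS2 (3.09) and the acute phase gene SAA1 (3.05), with adjusted p from 0.0309 to 0.0478. All 5 UC samples lay above the REF mean in each.

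Also higher in UC were the KDEL receptor KDELR3 (2.21), the chaperone partner SDF2L1 (1.68) and the translocon subunit SSR4 (1.39). Lower were the water channel AQP8 (-6.15), MEP1B (-5.50), the drug efflux pump ABCG2 (-5.33), the sulfate transporter SLC26A2 (-3.76) and the carnitine transporter SLC22A5 (-2.77). In CD against REF 26 genes passed in this fit, among them MEP1B (-3.15), ABCG2 (-2.96), the sterol regulator INSIG1 (1.00), the pentose phosphate enzyme PGD (0.86), the cytokine MIF (0.78) and the adhesion molecule ALCAM (0.61). With all 4 clusters as a block 4 genes passed in CD, namely PAGE2B (-0.48), PAGE2 (-0.47), PLIN1 (-0.79) and IGSF1 (-0.28).

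DUOX2, CXCL1 and MEP1B changed in CD and in UC, and 106 genes were shared between the 2 diseases. Simulations without effects called a median of 0 genes in CD and in UC, so their count of shared genes decides nothing. Over all genes the log2 differences of CD and UC correlated at r = 0.895, against a mean of 0.418 in the simulations, and the covariance was 0.235 against 0.0188. Genes are not independent replicates. Shared REF samples alone were argued against by the covariance with no REF sample on both sides, which was 0.212 on average over the 70 ways to split REF, and 2 of 100 splits of the labels REF, CD and UC, the real one included, gave as much (highest other 0.243). A structure of the samples shared by CD and UC, such as inflammation or a cluster, was not separated from this.

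A candidate explanation for the clusters is that the control arrays used as divisor held other RNA in the batches behind clusters 1 and 2 than in those behind clusters 3 and 4. OLFM4 kept to a range from 1.15 to 1.91 in 17 samples of clusters 3 and 4 but reached 7.71 in clusters 1 and 2, and over receptor-family genes CD samples of clusters 3 and 4 minus those of clusters 1 and 2 correlated with UC minus REF at r = 0.669 (rank 3 of 165 splits, and 7 beyond the chemokine score). Over all genes r was 0.612 (rank 15, and 39 beyond the chemokine score), which met the bound written beforehand against a divisor. Against treated CD minus REF r was 0.735 over all genes (rank 4, and 20 beyond the chemokine score) and 0.696 over receptor-family genes (rank 1, and 7 beyond it). The clusters were cut from correlations between these same samples, so high r values were partly fixed in advance and their ranks do not count for a divisor. The batch of each sample would test the candidate explanation, and that batch is not given in the sources used here.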
